A study of Homo sapiens with 635 samples.

How the data were processed

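The deposited data are 1 table of 23271 genes by 635 cells, each cell captured on a microfluidic chip and made into cDNA from polyadenylated RNA, per the labels' protocols. The values are FPKM (fragment counts scaled by transcript length and by the number of mapped fragments) made by the authors and deposited without log transformation; the unit was read from the values and from the name Cufflinks in the submitters' processing notes. Those notes name FastQC, TopHat, Cufflinks and Picard and the builds hg19 and GRCh37, without versions, roles or order, and filters are not given in the sources used here. FPKM sums per cell ranged from 110862 to 2035260, with a median of 465979, so the values do not add up to a common total. The annotation at hand is of another build, so genes are given by the symbols of the deposited table and no coordinates are printed; 19918 symbols are current, 2072 are older names and 1281 had no match in the reference tables. A total of 2347 genes were 0 in every cell, and 74.1% of all values were 0. An exact 0 can be a failed estimate as well as absent RNA.

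Each cell is 1 deposited sample, and cells are not replicates. Quartile and preparation were taken from the labels, and the replicate is the preparation. The 9 preparations are numbered 1 to 7, 9 and 10 after the labels. The 36 means over cells, 1 per preparation and quartile, entered the tests. They cover 634 cells, of which 162 were in Q1, 155 in Q2, 156 in Q3 and 161 in Q4; 142 of the Q4 cells and 16 of the Q3 cells had ID4 listed at 0. ID4 was cut at different levels in different preparations, with nearly equal numbers of cells per quartile in each, so the bins were made within preparations and the preparation was a fixed block. This pairing comes from the labels. Deviations of means from their quartile's average correlated by 0.19 on average within a preparation (lowest 0.02) and by -0.05 between preparations, and 36 of 36 means matched their own preparation best.

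The quantity tested was the mean over cells of log2(FPKM + 1). The added 1 shrinks the differences of low genes. A difference also reflects the share of cells listed at 0, so it can be larger than the change in mean FPKM. Genes with an FPKM of at least 1 in at least 10% of cells were tested, 11344 with ID4 and 11343 without it. limma 3.58.1 in R 4.3.3 fitted all 4 quartiles and the preparations in 1 model with an intensity trend in the prior variance, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Every adjusted p of a gene is from that limma fit unless another test is named. Gene lists were tested with camera (two-sided, preset correlation of 0.01), beside camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction and called 8 lists. Of the 24 lists, 21 had at least 3 genes above the filter and were tested; of the mitochondrially encoded list, 0 of 13 members could be matched by symbol. They hold markers of undifferentiated and differentiating spermatogonia, meiosis, spermatids, Sertoli, Leydig, peritubular myoid and endothelial cells, leukocytes and red blood cells, and genes of the sort antigens, S phase, G2 and M phase, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded proteins, glycolysis, BMP, SMAD and ID signalling, GDNF and FGF signalling, retinoic acid, immediate early and heat shock response, the piRNA pathway, pluripotency and fetal germ cells, and DNA methylation and chromatin. Detection shares and genes per cell were compared by exact permutation of the signs of the 9 differences within preparations (two-sided), with Benjamini-Hochberg adjustment over the panel of 20 markers. The lists, tests, panel and rule for named genes were chosen before the data were examined.

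Named genes are ID4, and, among genes with an adjusted p under 0.05, a mean log2(FPKM + 1) of at least 1 in Q1 or Q4 and the same sign in at least 8 of 9 preparations, the 12 largest differences in each direction. Clones, pseudogenes, antisense and small RNAs, Y-linked genes and XIST are left out of that choice. To these come up to 4 members of each list with the smallest p, the fixed panel, and up to 3 genes in each direction per neighbouring comparison by the same rule.

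Read counts are unknown. Low FPKM of a gene step by whole reads, and comparing these steps between cells gave relative depths; 98.5% of pairwise estimates against 60 reference cells lay within 0.05 log2 of the fitted values. The limma procedure was tested on simulated data with the 11343 genes of the Q1 and Q4 comparison. Fitted quartile differences were removed, and 50 genes were changed at each size. It recovered 14% of genes changed by 0.5 log2, 80% of those changed by 1, 98% of those changed by 1.5 and 100% of those changed by 2. There was 1 false call among 147. The real comparison called 26 genes. Fewer calls make the adjusted threshold stricter, so the shares recovered there can be lower.

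Alternatives were pseudocounts of 0.1 and 10, the log2 of mean FPKM, other filters on low genes, no block or a random block, and detection as a covariate. Further ones were quantile normalization, equal cell medians, removal of cells with few genes or with somatic markers, and only the compared quartiles. The last were weights by cell number, other variance priors and leaving out each preparation. For equal cell medians, each cell's FPKM was scaled before the log to a common median of its genes with an FPKM of at least 1. Chosen after the data were seen were keeping the empty cell, covariates for relative depth, stress genes and S phase genes, and an exact permutation of list means. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.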

Results

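Transcriptomes of single spermatogonia from adult human testis were binned by their level of ID4 mRNA, which encodes an inhibitor of DNA binding used as a marker of spermatogonial stem cells in the mouse. The cells had been sorted for low EPCAM and THY1, for ITGA6, and against HLA class I and ITGA5. Of 635 deposited cells, 1 in Q3 was listed at 0 for every gene and was left out. The 634 cells used came from 9 preparations, and 25.6% were in Q1 (highest ID4), 24.4% in Q2, 24.6% in Q3 and 25.4% in Q4 (lowest ID4). Each preparation held cells of all 4 quartiles, with 13 to 22 cells per preparation and quartile. Genes with an FPKM of at least 1 numbered 5448 per cell at the median, with a range of 2398 to 7667. The read depth of each cell is unknown, but the depth of cells relative to each other could be recovered and had 5th and 95th percentiles of -1.18 and 1.03 on the log2 scale. The labels do not say which donors each preparation came from. The p-values measure how far differences between quartiles within a preparation varied over the 9 preparations, and not a spread between donors.

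ID4 itself was read first, as a check of the labels. Its median FPKM was 48.8 over the Q1 cells, 17.2 over Q2 and 1.99 over Q3. ID4 was listed at 0 in 88.2% of the Q4 cells and in 10.3% of the Q3 cells. In no preparation did the lowest ID4 value of a quartile lie below the highest value of the next one. In preparations 1, 5, 7 and 10, however, the lowest Q3 value and the highest Q4 value were both 0. There the deposited ID4 values cannot tell which cells listed at 0 belong to Q3 and which to Q4. The mean log2(FPKM + 1) of ID4 was 5.72 ± 0.27 in Q1 and 0.08 ± 0.11 in Q4 (SD, n = 9 preparations), and since ID4 defined the bins it was left out of all counts.

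The comparison of Q1 with Q4 asked which other genes differed between ID4-high and ID4-low spermatogonia. ID2, a paralogue of ID4 in the same family of inhibitors of DNA binding, was higher in Q1 by 2.53 ± 0.26 on the log2(FPKM + 1) scale (SE, n = 9 preparations, limma adjusted p = 7.3e-09). It was higher in 9 of 9 preparations, and its mean FPKM was 172 ± 88 in Q1 and 61.5 ± 37.6 in Q4 (SD). SPINK2, a serine protease inhibitor of the male germline, was higher by 1.73 ± 0.33 (SE, adjusted p = 0.00573), with mean FPKM of 231 ± 65.4 in Q1 and 125.2 ± 48.7 in Q4 (SD). CDKN3, a phosphatase that acts on cyclin-dependent kinases, was lower in Q1, with a difference of -1.96 ± 0.32 (SE, adjusted p = 0.000871) and a lower mean in 8 of 9 preparations. MYCN, a MYC family transcription factor, was also lower, at -0.86 ± 0.18 (SE, adjusted p = 0.022).

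**Figure D1:**
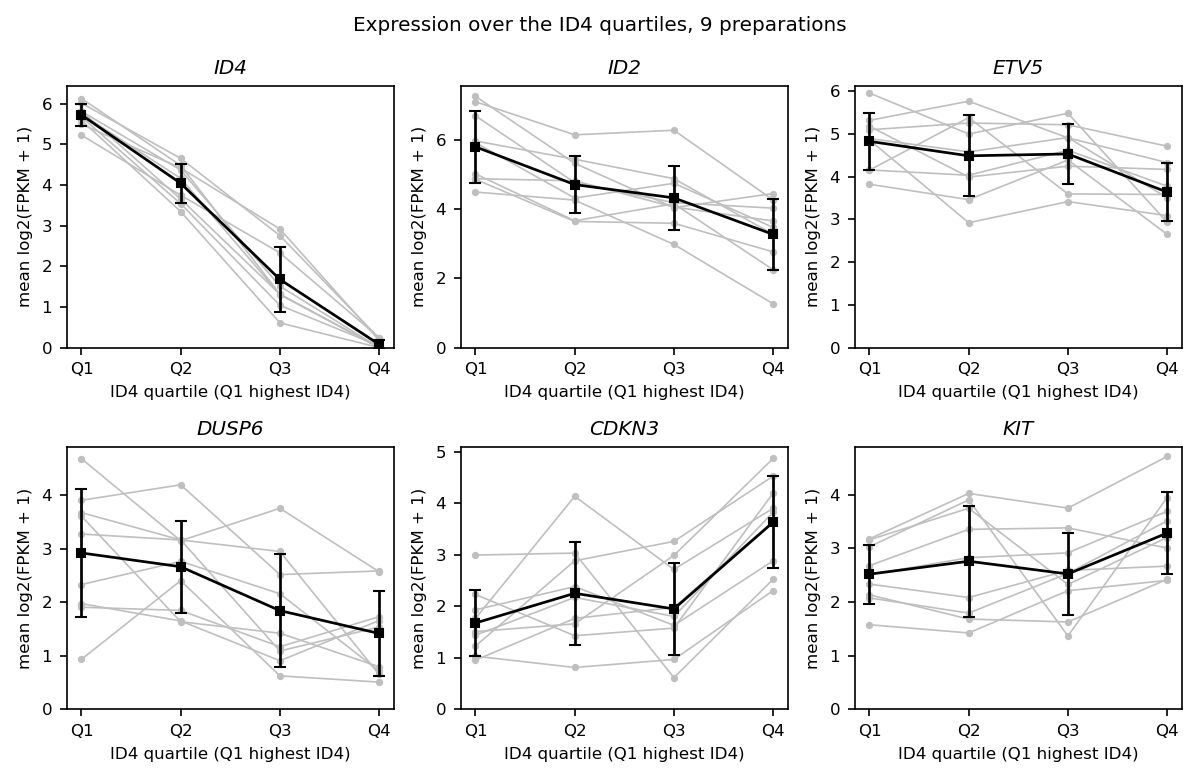
Mean log2(FPKM + 1) of 6 genes (vertical axes) in the 4 ID4 quartiles (horizontal axes). Grey lines join the quartiles of 1 preparation, and black squares with bars give the mean and SD of 9 preparations. ID2 went from a mean of 5.80 in Q1 to 3.27 in Q4, and CDKN3 from 1.67 to 3.63.

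Across 11343 genes tested with limma, 1264 had an unadjusted p under 0.05, where chance alone gives about 1 in 20. An adjusted p of 0.05 was passed by 26 genes, of which 23 were higher and 3 were lower in Q1. Signalling genes were among the higher ones. DUSP6, a phosphatase induced by ERK signalling, differed by 1.51 ± 0.29 (SE, adjusted p = 0.00972), and ETV5, a transcription factor downstream of GDNF and FGF, by 1.19 ± 0.27 (SE, adjusted p = 0.0398). The RNA-binding protein L1TD1 of pluripotent cells (1.43 ± 0.29), the germline ADP/ATP carrier SLC25A31 (1.39 ± 0.26) and the ubiquitin-like modifier UFM1 (1.44 ± 0.26) were higher as well (SE). The remaining genes among the largest increases were TXNIP, PNRC1, ZFYVE16, IRF2BP2 and SERINC5, with differences between 1.36 and 1.18. DNAJB1 and PFKL were higher too and are named as members of their lists. Outside the rule for named genes, and chosen after their values were seen, the other higher genes were COMMD3, DPYSL2, IGF2BP1, MFF, PTPRD, SNORA12, SOS1, TDP2 and YPEL2. The third lower gene, also outside the rule, was the short non-coding RNA SNAR-C3, at -2.28 ± 0.29 (SE, adjusted p = 1.93e-06) and lower in 9 of 9 preparations. SNAR-C3 belongs to a family of near-identical copies, so its FPKM is uncertain, and the 22 SNAR genes together took a median of 10.2% of a cell's FPKM total. Of the 26 genes, 15 were ordered over the 4 quartiles, ID2 and DUSP6 among them, while ETV5 and CDKN3 were not. The genes were chosen for their difference between Q1 and Q4, so this count is no test of a graded change.

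**Figure D2:**
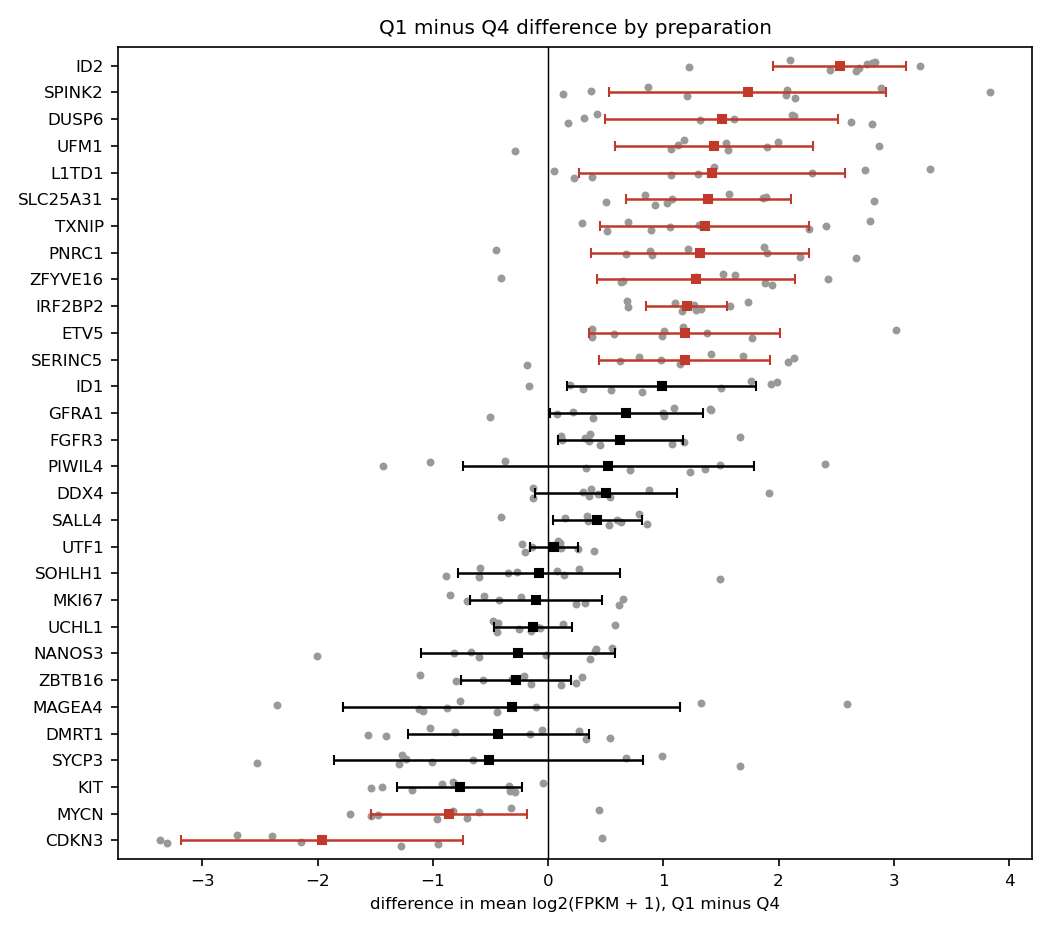
Difference in mean log2(FPKM + 1), Q1 minus Q4 (horizontal axis), for the genes with the largest changes and the marker panel. Grey points are 9 preparations, squares with bars are their mean and SD, and red marks genes with a limma adjusted p under 0.05, from ID2 at 2.53 to CDKN3 at -1.96.

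The number of genes depended on single preparations, being 9 without preparation 3, 4 without preparation 5 and 10 without preparation 9. The balance of directions depended on scaling: quantile normalization gave 17 higher and 16 lower genes, the log2 of mean FPKM gave 1 higher and 5 lower, and the number of genes detected as a covariate gave 5 higher and 5 lower. All 26 genes kept their direction in these settings, and ID2 passed the threshold in each of its 29 alternatives, CDKN3 in 28, ETV5 in 11, SNAR-C3 in 25, and MYCN in 15 of its 28. The other 21 genes passed in between 8 (COMMD3) and 26 (SLC25A31) of 29 alternatives, DNAJB1 in 10 and PFKL in 11.

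Markers of undifferentiated spermatogonia were higher in Q1 as a group (camera adjusted p = 0.013 with a preset correlation, and adjusted p = 0.0634 with an estimated correlation), with 18 of 27 tested members positive. Among them L1TD1 and ETV5 passed over all genes tested, and 4 members passed when adjusted over the list alone, which added NANOS2 (0.73 ± 0.18, SE), a repressor of differentiation, and SERPINE2 (0.91 ± 0.31, SE). GFRA1, the GDNF co-receptor, had a difference of 0.68 ± 0.26 (SE, adjusted p = 0.288), and FGFR3 of 0.63 ± 0.23 (SE, adjusted p = 0.255), and neither passed over all genes. UTF1 (0.05 ± 0.09), ZBTB16 (-0.28 ± 0.22) and UCHL1 (-0.13 ± 0.21) did not pass either (SE). The differentiating list was lower in Q1 (adjusted p = 0.00392, and adjusted p = 0.0634 with an estimated correlation), with 9 of 11 members negative and 0 passing over all genes. Adjusted over the list alone, DMRTB1 (-0.71 ± 0.21), SOHLH2 (-0.85 ± 0.26) and the receptor KIT (-0.77 ± 0.27) were lower, whereas the DNA methyltransferase DNMT3A (0.66 ± 0.24) was higher (SE). KIT was lower in 9 of 9 preparations, with an adjusted p of 0.227 over all genes.

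Genes of BMP, SMAD and ID signalling were higher in Q1 (camera adjusted p = 3.61e-05, and adjusted p = 0.00174 with an estimated correlation), and the list mean was higher in 9 of 9 preparations by 0.49 ± 0.17 (SD). Of 16 members tested, 14 were positive. ID2 passed over all genes, and 6 passed when adjusted over the list alone. These included the E protein TCF12 (1.02 ± 0.26), ID1 (0.99 ± 0.29) and the BMP pseudoreceptor BAMBI (0.72 ± 0.22) (SE). The GDNF and FGF signalling list was higher too (adjusted p = 0.00112, and adjusted p = 0.0634 with an estimated correlation). In that list DUSP6 and ETV5 passed over all genes, and 6 of 17 members passed when adjusted over the list alone, among them the feedback inhibitors SPRY2 (0.57 ± 0.18) and SPRY1 (0.41 ± 0.15) (SE). Of its 22 genes, 6 are also in another list, as are 12 of the 31 matched genes of the undifferentiated list. ETV5 is in both, so these lists are not independent. The piRNA pathway list was higher (adjusted p = 0.0087, and adjusted p = 0.0892 with an estimated correlation), with 0 of 21 members passing over all genes and 3 adjusted over the list alone: GTSF1 (0.80 ± 0.27), the RNA helicase DDX4 (0.50 ± 0.17, and 0.33 without preparation 5) and the piRNA methyltransferase HENMT1 (0.48 ± 0.17) (SE).

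**Figure D3:**
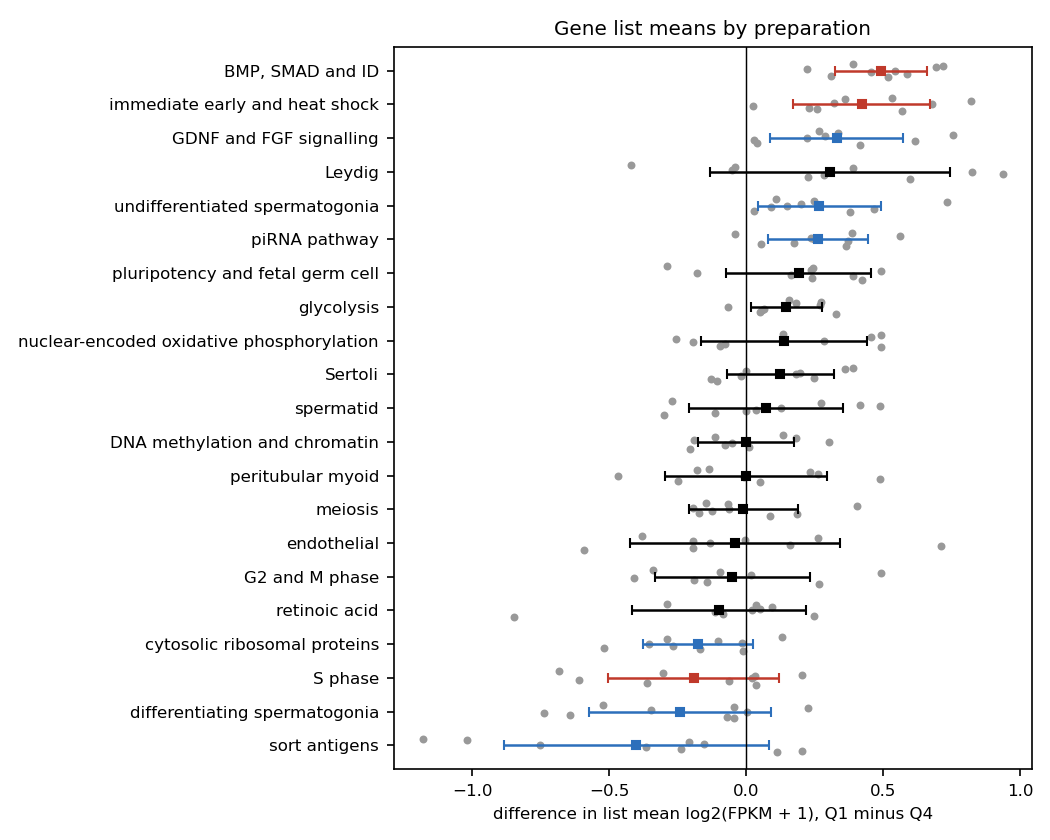
Difference in the mean log2(FPKM + 1) of each gene list, Q1 minus Q4 (horizontal axis), for 21 lists. Grey points are 9 preparations and squares with bars their mean and SD; red lists passed camera with both a preset and an estimated correlation, blue lists only with the preset one, and black lists with neither. The BMP, SMAD and ID list had a mean of 0.49 and the S phase list of -0.19.

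S phase genes were lower in Q1 (camera adjusted p = 4.15e-05, and adjusted p = 0.027 with an estimated correlation), with 23 of 34 members negative and 0 passing over all genes. Adjusted over the list alone, the replication factors CDC45 (-0.87 ± 0.26) and MCM6 (-0.84 ± 0.26) were lower (SE), each in 9 of 9 preparations. The S phase list mean itself was higher in Q1 in 4 of 9 preparations; relative to the mean of all genes tested, it was lower in 8 of 9 (exact permutation adjusted p = 0.041). That test did not pass for 3 of the 9 lists called by camera: piRNA pathway (adjusted p = 0.0586), sort antigens (0.0615) and cytosolic ribosomal proteins (0.0729). For G2 and M phase genes the test did not pass (adjusted p = 0.181), except without preparation 1 (0.0499) and in 3 other alternatives, in a range of 0.00541 to 0.7755, and MKI67 had a difference of -0.10 ± 0.16 (SE), between -0.20 without preparation 6 and -0.011 without preparation 10. Cytosolic ribosomal protein genes were lower in Q1 by a median of -0.18, with 62 of 74 members negative (adjusted p = 1.86e-10, and adjusted p = 0.0899 with an estimated correlation), and RPL27 (-0.52 ± 0.13) and RPS2 (-0.79 ± 0.23) were lower when adjusted over the list alone (SE). Their reads can be shared with processed pseudogenes, which leaves their FPKM uncertain.

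Immediate early and heat shock genes were higher in Q1 (adjusted p = 3.61e-05, and adjusted p = 0.0074 with an estimated correlation), and all 12 members tested were positive. The HSP40 co-chaperone DNAJB1 passed over all genes (1.16 ± 0.27), and HSP90AA1 (0.47 ± 0.14) and DUSP1 (0.69 ± 0.25) when adjusted over the list alone (SE). The list of sort antigens was lower (adjusted p = 0.0435, and adjusted p = 0.0898 with an estimated correlation) on 3 tested members, of which EPCAM had a difference of -0.77 ± 0.26 (SE), lower in 9 of 9 preparations. This list passed in 14 of 28 alternatives and did not pass without preparation 5 (adjusted p = 0.087), 7 (0.0524), 9 (0.1411) or 10 (0.1198), in a range of 0.021 to 0.2672 over the alternatives. In all, 9 of 21 lists passed with the preset correlation and 3 with the estimated one (BMP, SMAD and ID, S phase, and immediate early and heat shock).

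Markers of other testis cell types did not pass between Q1 and Q4 as lists. The camera adjusted p was 0.377 for Sertoli (8 of 17 matched genes tested) and 0.299 for Leydig genes (3 of 12). It was 0.613 for peritubular myoid (10 of 15) and 0.456 for endothelial genes (3 of 12). Genes with an FPKM of at least 1 in under 10% of cells were not tested, so these results say little about rare somatic cells. Adjusted over the Leydig list alone, DLK1 was higher in Q1 (0.84 ± 0.28, SE), in 6 of 9 preparations. In the endothelial list the median was 0.00097 while the mean was -0.04 and the test pointed down. The leukocyte list had 2 members above the filter, CD74 at 0.62 ± 0.16, which passed over the list alone, and CD3D at -0.21 ± 0.17 (SE), and the red blood cell list 1, so neither was tested as a list. Cells with an FPKM of at least 10 for 3 or more markers of a somatic list made up 40.7% of Q1, 47.7% of Q2, 39.1% of Q3 and 34.8% of Q4, and without these 257 cells 8 genes passed, 3 higher and 5 lower. This rule does not by itself identify somatic cells, as the labels call every cell a spermatogonium. The Sertoli list member TJP1, for example, had a mean log2(FPKM + 1) of 6.63 in Q1 and 6.28 in Q4. Meiosis genes (adjusted p = 0.316) and spermatid genes (adjusted p = 0.894) did not pass, and SYCP3 had a difference of -0.51 ± 0.34 (SE), which was -0.26 without preparation 3 and -0.79 without preparation 1.

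The share of cells with a detectable marker was compared for a panel of 20 genes. ID2 was detected (FPKM of at least 1) in 89.9% ± 7.9 of Q1 cells and 59.3% ± 14.3 of Q4 cells (SD, n = 9 preparations). ETV5 was detected in 90.7% ± 9.5 against 70.5% ± 15.7, and FGFR3, a surface receptor of undifferentiated spermatogonia, in 77.2% ± 13.7 against 57.7% ± 13.7 (SD). These 3 genes differed in the same direction in 9 of 9 preparations and passed an exact permutation test of sign changes (two-sided, p = 0.0039, the smallest that 9 pairs allow, adjusted p = 0.026 over the panel). For FGFR3 the call was lost at an FPKM of at least 10, where the difference was 6.7 percentage points. GFRA1 (64.4% ± 11.9 against 45.9% ± 12.8, exact adjusted p = 0.104), ID1 (43.2% ± 16.9 against 24.4% ± 12.0, exact adjusted p = 0.0938) and SALL4 (27.4% ± 12.3 against 16.3% ± 12.8, exact adjusted p = 0.0781) did not pass (SD). KIT was detected in 55.8% ± 12.4 of Q1 and 61.5% ± 15.3 of Q4 cells (SD, exact adjusted p = 0.647), and DDX4 in 98.7% ± 2.7 and 99.3% ± 2.0 (SD). STRA8 was detected in 0% of Q1 cells and 1.17% ± 3.51 of Q4 cells (SD), and the quartiles differed in 1 of 9 preparations only.

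**Figure D4:**
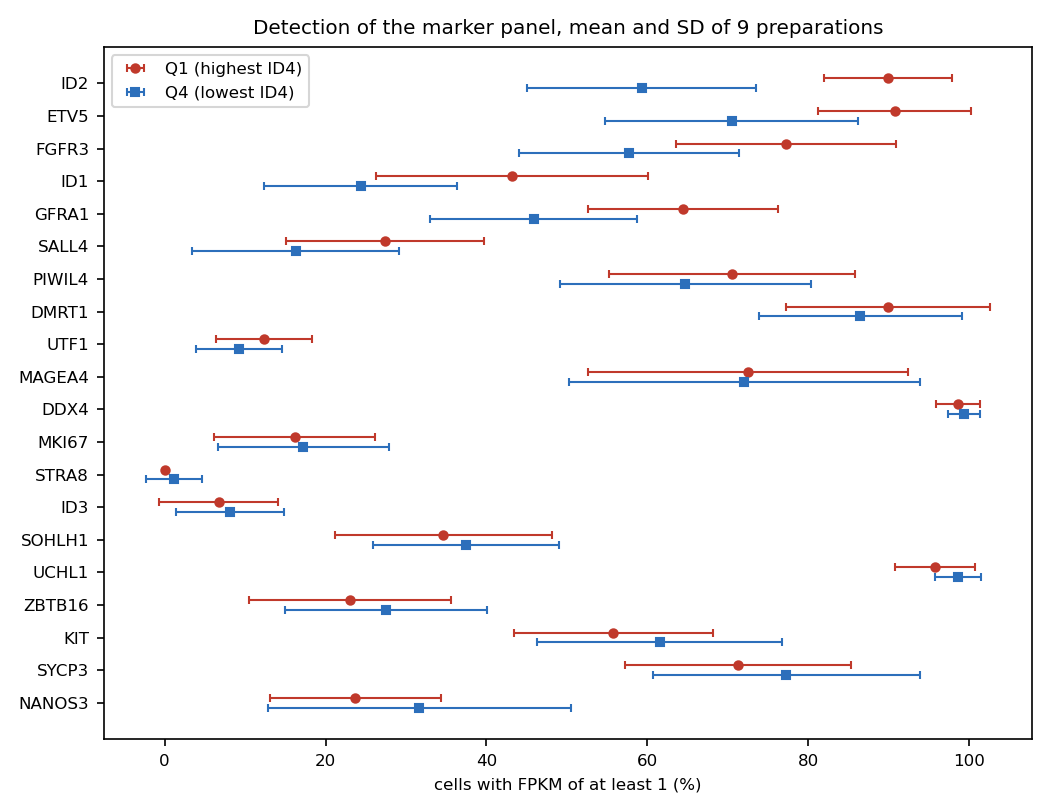
Share of cells with an FPKM of at least 1 (horizontal axis, %) for 20 panel genes in Q1 (red circles) and Q4 (blue squares), as mean and SD of 9 preparations; bars may pass 0 or 100 because they are symmetric. ID2 was detected in 89.9% of Q1 and 59.3% of Q4 cells.

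The number of genes detected per cell was 5354 ± 607 in Q1 and 5156 ± 650 in Q4 (SD, n = 9 preparations). The mean difference of 198 genes, higher in Q1 in 7 of 9 preparations, did not pass the exact permutation test (two-sided p = 0.0586), whereas counting every FPKM above 0 gave a difference of 223 genes with an exact p of 0.0313 (adjusted p = 0.0729 over 7 measures per cell), and an FPKM of at least 10 gave 108.2 genes, higher in Q1 in 5 of 9 preparations (exact p = 0.1367). Leaving out preparation 2 or preparation 4 also brought the difference past the threshold (231 and 237 genes, exact p = 0.0391 in each case), while without any of the other 7 it did not pass (exact p from 0.0625 to 0.1172), and without preparation 7 it fell to 123.7 genes.

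Neighbouring quartiles differed in few genes. Between Q1 and Q2, 2 genes passed in limma: SNAR-C3 was lower in Q1 (-1.60 ± 0.29, SE, adjusted p = 0.0143) and the uncharacterised locus LOC100505875 was higher (0.86 ± 0.17, SE, adjusted p = 0.031), both named after their values were seen. Between Q2 and Q3, PON3, a paraoxonase, was higher in Q2 (1.42 ± 0.27, SE, adjusted p = 0.0367) in 9 of 9 preparations. Between Q3 and Q4, LRRC42 was higher in Q3 (1.45 ± 0.29, SE, adjusted p = 0.0411), and CDKN3 was lower in Q3 (-1.69 ± 0.32, SE, adjusted p = 0.0411) in 9 of 9 preparations. CDKN3 thus had means of 1.67, 2.25, 1.95 and 3.63 from Q1 to Q4. At an unadjusted p under 0.05 there were 597, 689 and 847 genes for the 3 neighbouring comparisons. Without any difference, about 1 in 20 of the 11343 genes tested would fall under it. These counts, and the 664 of the next contrast, thus include many genes expected by chance. The contrast of Q1 and Q4 with Q2 and Q3 gave 0 genes in limma and 664 at an unadjusted p under 0.05. It sees only a bend of the outer against the middle bins, and other departures from a straight line were not tested. These small counts fell to 0 under several alternatives and without several single preparations, among them preparation 5 for each of the 3 neighbouring comparisons.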

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

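The tests of other short RNAs and of the balance of directions under quantile normalization were chosen only after the results they bear on had been seen, and the spread of the test values with 1 preparation left out was added then too. Among the groups of 9 preparations examined, 7 (4.52%) had 1 preparation far from the others, where chance gives about 1 in 20. NANOS2 differed between Q1 and Q4 by 2.06 on the log2 scale in preparation 4, against 0.12 to 1.05 in the others. NR2F2, a Leydig list member, differed by -0.46 in preparation 10, against 0.13 to 0.50. CENPF differed by 0.78 in preparation 1, against -1.49 to -0.44, so that it was lower in Q1 in the other 8. DDX4 differed by 1.92 in preparation 5, against -0.13 to 0.88, and SOHLH1 by 1.49 in preparation 1, against -0.88 to 0.27. The mean of the retinoic acid list differed by -0.85 in preparation 1, against -0.29 to 0.25. The Q1 cells of preparation 10 had a mean log2 relative depth of 0.57, against -0.23 to 0.15 for the Q1 cells of the others.

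The first pattern weighed is the set of 23 genes higher in Q1. Their median difference was 1.08 (median SE 0.29) with the number of genes detected as a covariate and 1.20 (0.26) without. The ratio of 0.896 stayed between 0.88 and 0.946 without any 1 preparation, although only 5 of the 23 kept an adjusted p under 0.05. With relative depth as a covariate the ratio was 1.07 and 18 of the 23 passed. With the mean of the immediate early and heat shock list the ratio was 0.949 for the 22 genes outside that list, of which 2 passed. For these 22 the median difference went from 1.24 to 1.18 and the median SE from 0.26 to 0.38. These values argue against detection or depth, as these covariates measure them, as the whole cause of the differences of these 23 genes, which were chosen on the same data. For a stress response the covariate cannot decide, as the SE grew and the median difference of all genes tested went from 0.042 to -0.046. With genes detected as a covariate that median moved less, to -0.010, and the SE grew less, to 0.29. For the surplus of higher over lower genes an effect of detection cannot be told apart from a difference between the quartiles. The share of higher genes went from 88.5% to 51.5% with quantile normalization, which by itself evens out the directions, as lower genes rose from 3 to 16 and higher ones fell from 23 to 17. A difference between ID4-high and ID4-low cells stays open for the genes themselves.

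The second pattern is the low SNAR-C3 of Q1. With the number of genes detected as a covariate the difference was -2.16 ± 0.32 (SE) against -2.28 ± 0.29 without, a ratio of 0.946, and the log2 of the summed SNAR FPKM differed by 0.924 of the SNAR-C3 difference, which argues against detection and against reads moving between copies as its cause. Other short RNAs had a median difference of 0.32 (interquartile range 0.24 to 0.55) with 2 of 21 lower in Q1, which argues against a length correction shared by short RNAs. SNAR-C3 did not pass in 4 of its 29 alternatives: at -1.06 with the log2 of mean FPKM (adjusted p = 0.139), -1.24 with quantile normalization (0.162), -1.84 with the stress covariate (0.1123) and an unchanged -2.28 with no replicate block (0.1485). With equal cell medians it was at -2.22 (7.16e-06), and the range over all alternatives was 2.1e-07 to 0.162. The sum of SNAR FPKM was 73357 ± 57594 in Q1 and 119975 ± 57223 in Q4 (SD, n = 9, exact permutation p = 0.0117). With equal cell medians all 26 genes still passed, and in the main fit the median difference of all genes tested was 0.042. These values argue against an effect of the very high SNAR values on scale as the cause of the other called genes. A difference between ID4-high and ID4-low cells stays open for SNAR-C3.

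The third pattern is the immediate early and heat shock list, higher in Q1. The list mean was higher in Q1 in 9 of 9 preparations, which decides nothing on handling that differed between preparations, as the quartiles were compared within them. With the number of genes detected as a covariate the median difference of the list was 0.27 against 0.38 without, a ratio of 0.727 that ranged from 0.534 to 0.866 without any 1 preparation. A contribution of detection therefore cannot be told apart from a difference between the quartiles, because the ratio lies between the bounds set for either. A response of cells to dissociation that depends on their ID4 level was not tested.

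Labels were swapped within preparations in 99 drawn arrangements of 256, and the real labels made the total 100. For Q1 and Q4, 1 of 100 arrangements (the real one) gave as many as 26 genes, and the highest other gave 5, so chance could be excluded. The same held for the gene lists, with 1 of 100 and 9 lists against at most 7 in the others, although the others called 1 list at the median, so single lists with a preset correlation carry less weight than the total. Without correction for the 5 comparisons, chance could also be excluded for the 2 genes between Q1 and Q2 (1 of 100, highest other 1) and, less firmly, for the 2 between Q3 and Q4 (2 of 100, as 1 other arrangement also gave 2). It could not be excluded for the 1 gene between Q2 and Q3 (7 of 100, highest other 1). For the 0 genes of the outer against the middle quartiles the swaps decide nothing, since no arrangement can give fewer (100 of 100, highest other 1).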

How the results depend on the processing

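The covariates for relative depth, stress genes and S phase genes, the kept empty cell and the exact permutation of list means were chosen after the data were seen. The genes called between Q1 and Q4 kept their direction in every setting that tested them, 25 of the 26 with the 25% filter and 26 in the others. Their number of 26 became 41 with a pseudocount of 0.1, 17 with 10, 6 with the log2 of mean FPKM (1 shared), 52 with equal cell medians, 8 without cells holding somatic markers (5 shared), 11 with no filter on low genes (10 shared), 10 with genes detected as a covariate (7 shared), 55 with weights by cell number (26 shared), 14 with only the compared quartiles, 4 with the stress covariate (3 shared) and 16 with the S phase covariate (11 shared), and ranged from 4 (without preparation 5) to 36 (without preparation 2) when 1 preparation was left out, with 9 without preparation 3 and 10 without preparation 9. Without the replicate block 2 genes remained (both shared), and with the block as a random effect 26 (19 shared). No filter tests more genes and fewer cells or quartiles give fewer values; for the other settings the cause was not tested. The 2 genes between Q1 and Q2 became 0 with a pseudocount of 10, the log2 of mean FPKM, cells with somatic markers left out, no filter, no replicate block, the random block, quantile normalization, either other variance prior, the stress or S phase covariate or only the compared quartiles, 1 with the 25% filter or genes detected as a covariate, and 0 to 2 without 1 preparation. The 1 gene between Q2 and Q3 became 0 with a pseudocount of 10, the log2 of mean FPKM, cells with somatic markers left out, no filter, no replicate block, the random block, quantile normalization, weights by cell number, no variance trend, the S phase covariate or only the compared quartiles, and was 0 to 1 without 1 preparation. The 2 genes between Q3 and Q4 became 0 with a pseudocount of 10, cells with somatic markers left out, no filter, no replicate block, no variance trend or the depth, stress or S phase covariate, 1 with the random block, genes detected as a covariate, quantile normalization or the empty cell kept, and 0 to 3 without 1 preparation. The contrast of outer with middle quartiles stayed at 0 except for 1 gene without preparation 4. The 9 lists became 3 with an estimated correlation and 4 with the S phase covariate, and were 6 to 10 in the other settings, 6 with the exact permutation of list means; the BMP, SMAD and ID list passed in all 28 alternatives. With the S phase covariate the undifferentiated, differentiating, piRNA, sort antigen and S phase lists no longer passed, and with the stress covariate the undifferentiated, piRNA, sort antigen and stress lists. The undifferentiated list also did not pass with the log2 of mean FPKM (adjusted p = 0.112) or the 25% filter (0.0514), nor the piRNA list with the log2 of mean FPKM (0.1796), in ranges of 0.00262 to 0.112 and 0.00247 to 0.1951. Of the lists that did not pass, the oxidative phosphorylation list turned direction in 4 alternatives (the log2 of mean FPKM, cells with somatic markers left out, and genes detected or the stress list as a covariate), the spermatid list in 5 (no filter, genes detected as a covariate, and without preparation 6, 7 or 9), the peritubular myoid list in 2 (cells with somatic markers left out and without preparation 5), and the endothelial and retinoic acid lists with no filter. The random block and the variance priors were not run for lists, and no cell had fewer than 2000 genes, so that setting removed none. Genes detected per cell passed at any FPKM above 0 (223) before adjustment over measures, did not at an FPKM of at least 10 (108.2), and ranged from 123.7 to 237 without 1 preparation. Directions turned for NANOS3 with the log2 of mean FPKM (0.57), MKI67 (0.094) and UTF1 (-0.011) with the S phase covariate, and SOHLH1 with cells with somatic markers left out (0.29) and without preparation 3 (0.023, in a range from -0.27 over the preparations left out). None of these genes passed in any setting, and the cause was not tested. Read depth per cell is unknown, which limits statements on genes listed at 0.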

Other observations

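PFKL, the liver form of phosphofructokinase, was higher in Q1 by 0.79 ± 0.18 (SE, limma adjusted p = 0.0427), at low means of 1.13 and 0.34. ALDOA (0.63 ± 0.19, SE) joined it when adjusted over the glycolysis list alone. PFKP was lower (-0.44 ± 0.16, SE) in 7 of 9 preparations and PFKM higher (0.58 ± 0.28, SE) in 7 of 9, and neither passed. The list had 12 positive and 7 negative members and did not pass camera (adjusted p = 0.316). Among 74 nuclear-encoded oxidative phosphorylation genes 54 had positive differences, with a median of 0.13, and the list did not pass (adjusted p = 0.299) and turned direction in 4 of 28 alternatives. The pluripotency and fetal germ cell list did not pass (adjusted p = 0.198) except without preparation 5 (0.0489) and without cells holding somatic markers (0.0403), in a range up to 0.4506; its members DPPA2 (0.92 ± 0.33, SE) and DPPA4 (0.61 ± 0.26, SE) were each positive in 8 of 9 preparations.

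The DNA methylation and chromatin list had members on both sides (camera adjusted p = 0.377). The de novo methyltransferase DNMT3A was at 0.66 ± 0.24, while the maintenance methyltransferase DNMT1 was at -0.58 ± 0.22 and its partner UHRF1 at -0.45 ± 0.17 (SE), and none of them passed over all genes or over the list alone. The retinoic acid list did not pass (adjusted p = 0.299). Genes detected per cell did not follow the order of ID4, being highest in Q2 at 5557 ± 656 and higher there than in Q1 in 8 of 9 preparations (SD, exact permutation p = 0.0078, 1 of 4 comparisons of quartiles for this measure, unadjusted). The sum of FPKM per cell was lower in Q1 than in Q4 in 9 of 9 preparations, by a mean of -60909 (exact permutation p = 0.0039, adjusted p = 0.0273 over 7 measures per cell), and without SNAR genes the difference was -14291 (exact p = 0.223).

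One hypothesis was that the genes higher in Q1 may only follow a smaller share of cells in S phase. With the mean of the S phase list as a covariate, the median difference of the 23 genes was 1.26 (median SE 0.30) against 1.20 (0.26) without, a ratio of 1.05 that ranged from 0.866 to 1.07 without any 1 preparation. Of the 23 genes, 8 kept an adjusted p under 0.05. The median difference of all genes tested also rose with this covariate, from 0.042 to 0.076. The covariate therefore cannot decide whether S phase is the whole cause, and the hypothesis stays open. With the same covariate the undifferentiated, differentiating and piRNA lists no longer passed camera, and the cause was not tested.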
